A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

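Total RNA from 3 independent carbon-limited aerobic chemostat cultures was labelled with biotin by the one-cycle eukaryotic target assay and hybridized to 1 Affymetrix array per culture, per the labels' protocols. The values are the submitters' deposited probe set intensities on a linear scale, and the software GCOS is named in the submitters' processing notes. The probe summary method, its version, the background correction and any scaling are not given in the sources used here. The deposited intensities do not share a scale, since the mean signal after trimming 2% at each end was 101 in culture 1, 223 in culture 2 and 167 in culture 3. All values were above 0, and 1586 of them lay under 1.

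The table held 9335 probe sets, of which 60 were Affymetrix controls. Platform annotation gave 1 gene for 6504 of the others, several genes for 328, which were not named or used, and none for 2443. Genes were named through a RefSeq gene table (assembly R64), which matched all 6504, and no coordinates were taken from it. Each of 5656 genes was represented by the probe set whose name ends in digits and _at with no letter code, and otherwise by that with the higher mean signal. In 245 of the 315 genes with several probe sets these differed by more than 1 on the log2 scale. Letter-coded probe sets, as for SUF23, MFA1, HXT6, HXT7, TDH3, SSA1, RPS21A, RPS21B and the seripauperin (PAU) genes, can bind transcripts of near-identical family members. Their signals are therefore uncertain as measures of 1 gene.

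Signals were floored at 1 and taken to log2 as deposited, with no normalization in the main setting. Dim genes, under the 30th percentile of mean signal, were left out of comparisons between cultures, which leaves 3959 genes. With 1 group no test between groups was made and no p-value is given. For each of 37 gene lists the median deviation of not-dim members from their 3-culture mean was set against 10000 random lists of the same size matched on mean signal in 20 bins. A list with at least 5 not-dim members stands apart in the outer 0.5% at either end, and its SD is called larger or smaller than that of matched lists over the 99th or under the 1st. Matched lists carry the array-wide shift of genes of similar signal, so list shifts are relative to those genes and not to the median gene. The lists, the limits and these comparisons were chosen before the data were examined.

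The named genes are, by a rule also chosen then, 31 genes set in advance, the 15 not-dim genes with the largest log2 range, the 6 with the highest mean signal, and of each list the members with the highest and the lowest mean signal and the not-dim member with the largest SD. Genes named beyond the rule are said to be so. In the lists, DAN2 was read as PAU23 and HOR2 as GPP2 from synonyms, and the entry for the urea amidolyase gene of the nitrogen list was not matched.

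Alternatives were a common median, quantile normalization and cyclic loess (limma 3.58.1 in R 4.3.3), other limits for dim genes (none, 10th or 50th percentile, a mean signal of 12), log2(signal + 16), the mean over a gene's probe sets, list means, 10 bins and leaving out each culture. Scaling to the hybridization controls, plain-named probe sets only, a floor at the highest sense-strand control (26.3), and genes lying over 1 (log2) from both other cultures were added after the data were seen. All other steps used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. The list and range steps were tested on simulated data for 3959 genes, drawn with the spread each gene showed on these arrays, where all 200 genes changed 4-fold in 1 culture passed 2-fold at a common median, as did 4.36% of the unchanged genes. Since the spread was taken from these arrays, the 4.36% is no independent share for genes without a change. All 10 lists of 20 genes shifted by 0.3 were found, and 1 of 90 unshifted pairs of a list and a culture was. Simulated genes varied independently, so these rates do not hold for smaller lists or shifts, or for lists whose members vary together.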

Results

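Transcript signals were measured in 3 independent steady-state chemostat cultures of the budding yeast Saccharomyces cerevisiae, each on its own Affymetrix array, and these cultures form 1 group. A chemostat fixes the growth rate through the rate at which medium is fed, and glucose was the nutrient that limited growth. The dilution rate was 0.10 per h at 30 °C and pH 5.0, the feed held 7.5 g of glucose, 5.0 g of ammonium sulphate and 4.5 mg of zinc sulphate heptahydrate per litre, and dissolved oxygen stayed above 80% of air saturation. The strain is not given in the sources used here. The series title concerns transcription under carbon limitation in aerobic chemostats, and cultures with another limitation were not analysed here, so no contrast between conditions was made. The questions addressed are which gene groups gave signal in this condition and how closely the 3 cultures matched. Signals were available for 5656 genes, each represented by 1 probe set. A probe set is called dim here when its mean signal lay under the 30th percentile of these genes (48.3) and bright when it lay over the 90th (589.6), which describes brightness on the array and does not order genes by transcript abundance. The median signal of an array was 30.6 in culture 1, 70.9 in culture 2 and 52.5 in culture 3. Each SD of a signal therefore contains an array-wide difference, and the number of arrays (n = 3 throughout) limits the precision. Sense-strand control probe sets, which have no labelled target, reached 26.3, so signals of that size or less can be nonspecific.

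Most genes of glycolysis, the tricarboxylic acid cycle, the respiratory chain and ATP synthase were bright by their mean over the 3 cultures. Of 16 measured glycolytic genes, 15 were bright and none was dim, among them TDH3, a glyceraldehyde-3-phosphate dehydrogenase, at 6126 ± 762 (mean ± SD of deposited intensities, n = 3), the pyruvate kinase CDC19 at 3115 ± 838 and the hexokinase HXK2 at 1010 ± 404. PYK2, the minor pyruvate kinase, read 88.9 ± 46.4. Among 15 genes of the tricarboxylic acid cycle 12 were bright, with citrate synthase CIT1 at 1766 ± 537 and succinate dehydrogenase subunit SDH2 at 2510 ± 849, and the lowest signal of the list was that of CIT3 at 236 ± 89.8. Nuclear-encoded respiratory chain genes were bright for 18 of 20 members, including cytochrome c (CYC1, 1642 ± 588), COX6 of cytochrome c oxidase (1364 ± 588) and QCR7 (1991 ± 649), whereas the probe set of QCR8 was dim at 23.5 ± 16.02. Of 12 genes for ATP synthase subunits, 8 were bright, with ATP15 at 1766 ± 739 and ATP20 at 162 ± 81.9. The alcoholic fermentation list had 3 bright and no dim members among 6, with alcohol dehydrogenase ADH1 at 3651 ± 1209 and the pyruvate decarboxylase PDC6 at 56.4 ± 16.6.

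Transporters and enzymes for hexose uptake, gluconeogenesis and the use of other carbon sources ranged from bright to dim. In the high-affinity hexose transport list 4 of 6 members were bright, HXT6 at 3928 ± 1092 and HXT7 at 3386 ± 948, although these near-identical genes share probe sequence and their signals cannot be assigned separately with certainty. The low-affinity transporter HXT1 was dim at 13.6 ± 7.62 and HXT3 read 177 ± 73.1, so that 1 of 3 members of that list was dim and none bright. None of 16 genes for gluconeogenesis, the glyoxylate cycle and use of ethanol, acetate or lactate was dim and 9 were bright. They included ADH2, the ethanol-oxidising alcohol dehydrogenase, at 4931 ± 1178 and isocitrate lyase ICL1 at 665 ± 152, while FBP1 and PCK1, enzymes specific to gluconeogenesis, read 238 ± 90.5 and 177 ± 60.7. Among 16 genes of fatty acid oxidation and peroxisomes 6 were bright and 1 was dim, with FOX2 at 1660 ± 541 and DCI1 at 23.4 ± 4.18. For the use of galactose, sucrose and maltose 7 of 12 members were dim, with SUC2 at 0.29 ± 0.21, and MAL11 read 466 ± 221.

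Genes known from oxygen limitation included no bright member, and most mitochondrially encoded genes were dim. Of 18 measured hypoxic genes 9 were dim, with ANB1 at 21.1 ± 11.9, DAN1 at 18.8 ± 5.12 and AAC3 at 8.12 ± 1.51. The cell wall mannoprotein genes TIR1 and TIR3, known from anaerobic and cold growth, read 158 ± 76.2 and 200.1 ± 10.8. Of the 8 genes of the mitochondrial genome 6 were dim, with VAR1 at 1.87 ± 2.91, and OLI1 (2522 ± 423) and COX1 (856 ± 314) were bright. These signals describe brightness on the array and do not show how far the mitochondrial genome was transcribed.

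Nutrient-responsive lists differed in brightness. For zinc uptake and storage none of 16 members was bright and 3 were dim. The zinc transporter ZRT1 read 74.6 ± 38.2, its regulator ZAP1 was dim at 38.7 ± 20.7, and ADH4, ZPS1 and IZH1 read 85.7 ± 38.6, 162 ± 103 and 456 ± 235. Of 20 iron genes 6 were dim and 1 was bright, with the mannoprotein FIT3 at 895 ± 337, the multicopper oxidase FET3 at 280 ± 122 and ARN2 at 1.30 ± 0.44. In the copper list 1 of 7 members was dim and 1 bright, the transporter CTR3 at 930 ± 487. Of 26 nitrogen-regulated genes 7 were dim and 4 bright, with glutamate dehydrogenase GDH1 at 1487 ± 357, the ammonium permease MEP2 at 421 ± 155 and the general amino acid permease GAP1 at 364 ± 118. Phosphate-regulated genes had 5 dim and no bright members among 15, with the phosphate transporter PHO84 at 48.8 ± 22.5 and the acid phosphatase PHO5 at 3.83 ± 2.49. Sulphate assimilation and methionine synthesis had 8 bright and 1 dim member among 22, with MET17 at 3143 ± 1102 and MET3, the ATP sulphurylase, at 575 ± 264. Of 36 amino acid synthesis genes 18 were bright and none was dim, with the transcription factor GCN4 at 3098 ± 1019. Thiamine genes were dim for 5 of 11 and bright for THI7 (801 ± 320). The inositol and phospholipid list had 4 bright and 2 dim members among 13, with the inositol transporter ITR1 at 1350 ± 613, and ergosterol synthesis had 10 bright and 1 dim member among 23, with ERG25 at 3413 ± 601.

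Ribosomal protein, stress and chaperone genes were mostly bright, and ribosome biogenesis factors were not. Of the 138 cytosolic ribosomal protein genes listed, 81 had a probe set of their own, of which 74 were bright and 1, RPL7A at 7.52 ± 3.24, was dim. Ribosome biogenesis factors were bright for 3 and dim for 6 of 56, with TIF6 at 1071 ± 448. General stress genes were bright for 17 of 29 and dim for 3, with HSP12, a membrane-associated stress protein, at 4492 ± 804, DDR2 at 4856 ± 1196 and the catalase CTT1 at 29.4 ± 9.63. Chaperones were bright for 13 of 17, with SSA1 at 6312 ± 1137, antioxidant genes for 9 of 24, with the peroxiredoxin TSA1 at 2522 ± 829, and proteasome subunits for 12 of 32, with PUP3 at 1771 ± 724. None of 16 genes for glycogen and trehalose was dim and 2 were bright, with trehalose-6-phosphate synthase TPS1 at 524 ± 125, the phosphatase TPS2 at 748 ± 250 and glycogen synthase GSY2 at 333 ± 147. The remaining probe sets among the 6 with the highest mean signals were those of the cell wall proteins CCW12 (8109 ± 1064) and TIP1 (5915 ± 600.0) and the ribosomal proteins RPS21A (5713 ± 1726) and RPS21B (5487 ± 1481), a near-identical pair.

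Markers of mating type and cell cycle stage were read as checks on the kind of cell. Of 7 genes of MATa cells 2 were bright and 1 was dim, with the pheromone gene MFA1 at 2185 ± 1734 and the alpha-factor receptor STE2 at 173 ± 77.6. All 4 genes of MATalpha cells were dim, including the a-factor receptor STE3 at 36.0 ± 22.9 and SAG1 at 47.9 ± 18.5. Haploid-specific genes were dim for 5 of 14 and bright for RME1 (651 ± 241). Of 26 meiosis and sporulation genes 25 were dim, and IME1, their master regulator, read 73.1 ± 18.9. In the adhesin and filamentation list 6 of 9 members were dim, with FLO1 at 0.94 ± 0.52, and the transcription factor TEC1 was bright at 950 ± 273. G1 and S phase genes were dim for 6 of 21 with none bright, RNR1 reading 410 ± 51.8. G2 and M phase genes were dim for 5 of 21 and bright for 3, with the chitinase CTS1 at 1847 ± 956, and 2 of 4 measured histone genes were bright, with HTB1 at 1085 ± 474. Over all 37 lists, 5 had most of their measured members dim, and that number depends on the brightness limit, being 2 at the 10th percentile and 11 at the 50th.

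**Figure D1:**
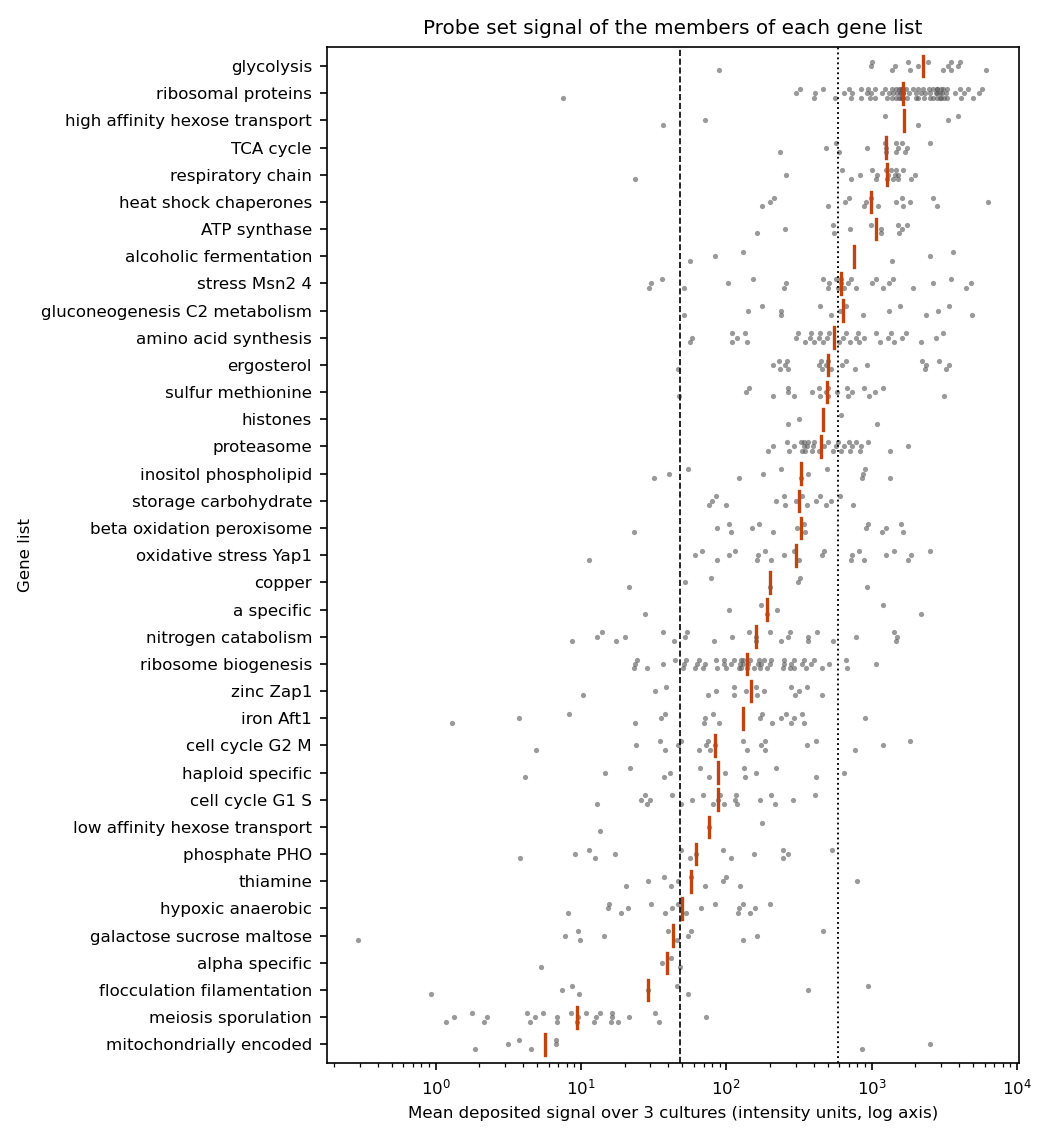
Mean deposited signal over the 3 cultures (log axis, intensity units) of each measured member of the 37 gene lists, 1 point per gene, with the list median as a vertical bar, the limit for dim (48.3) dashed and that for bright (589.6) dotted. Glycolysis, with 15 of 16 members bright, lies at the top, and the mitochondrially encoded list, with 6 of 8 members dim, at the bottom.

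Between cultures, nearly all genes shifted together. Of the 3959 genes that were not dim, 2989 (75.5%) differed by more than 2-fold between their highest and lowest deposited signal. The median log2 ratio was 1.21 for culture 2 over culture 1, a 2.31-fold difference, and 0.80 for culture 3 over culture 1, a 1.74-fold difference. After the arrays were brought to a common median, 138 genes (3.49%) differed by more than 2-fold, and the median SD of log2 signal fell from 0.63 to 0.180. Deposited log2 signals correlated across not-dim genes, which are not independent replicates, with r = 0.965 for cultures 1 and 2, 0.978 for cultures 1 and 3 and 0.966 for cultures 2 and 3, and no pair of arrays held identical values. The count of genes rested mostly on the difference between cultures 1 and 2. It was 125 without culture 1, 941 without culture 2 and 2873 without culture 3.

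The 15 genes with the widest range of deposited signal included MFA1, with 467 in culture 1, 3934 in culture 2 and 2153 in culture 3, which made a log2 range of 3.07. MEF1, a mitochondrial translation elongation factor, read 155, 35.9 and 244 in cultures 1, 2 and 3, and the glutathione transferase GTT2 read 45.5, 16.6 and 91.1, the value in culture 2 lying under the limit for nonspecific signal. Both belong to 8 probe sets low in culture 2 whose numbers fall within a run of 150. The tropomyosin TPM1 was lowest in culture 3, with 152 against 364 and 815 in cultures 1 and 2. The others were CIN4, YLL054C, MOH1, IZH4, NTO1, GAA1, RTT105 and the RNA genes SUF23, SUF17, YNCP0023W and YNCE0004C, whose probe sets carry a family code. In 12 of the 15 the lowest signal was in culture 1, the array with the lowest median. At a common median 12 of the 15 ranged over more than 1 on the log2 scale with signals floored at the 26.3 of the sense-strand controls, which left out YLL054C, NTO1 and RTT105, with 3.32 for MEF1, 2.04 for TPM1 and 1.87 for MFA1. By contrast the common-median SD of log2 signal was 0.03 for HXK2, 0.07 for MEP2, 0.08 for PCK1, 0.09 for FBP1, GSY2 and STE2, and 0.28 for actin (ACT1, 3165 ± 777).

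**Figure D2:**
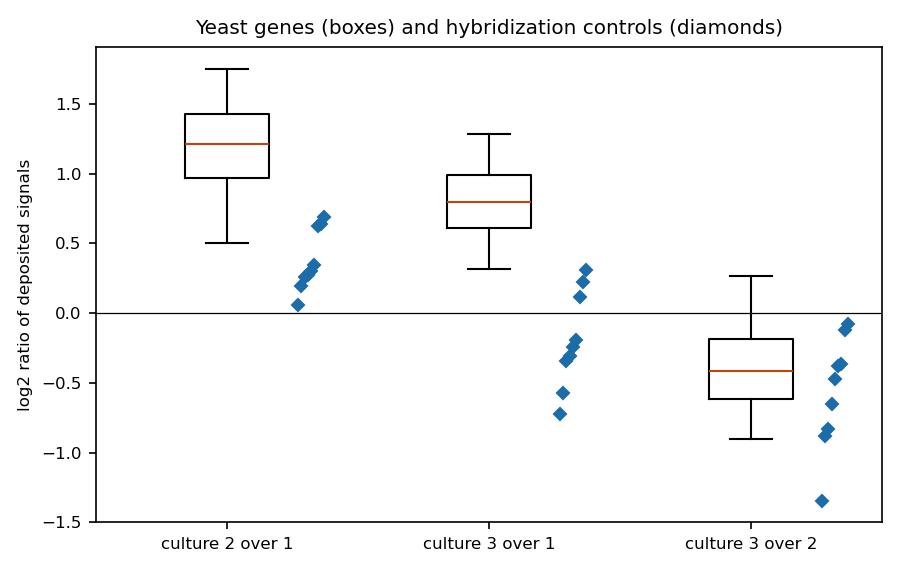
Log2 ratio of deposited signals for each pair of cultures, with boxes for the 3959 not-dim yeast genes (median, quartiles, whiskers at the 5th and 95th percentiles) and diamonds for the 9 bacterial hybridization control probe sets. The yeast medians are 1.21, 0.80 and -0.41, against control medians of 0.31, -0.25 and -0.47.

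Against lists of matched signal, ribosomal protein genes and genes of MATa cells stood higher in culture 2, and stress genes stood lower there. The array-wide shift of culture 2 was 0.545, as the median of not-dim genes against its 3-culture mean. Ribosomal protein genes followed it with a median deviation of 0.563, while their matched lists had 0.447. Stress genes had 0.377 against 0.521 in matched lists. Only a list's own members were left out of its matched lists, so ribosomal protein and stress genes could be drawn for each other. Their opposite shifts are therefore not separate. The 80 not-dim ribosomal protein genes lay 0.12 (log2) above random lists of matched signal in culture 2, with 63 of 80 on that side, and -0.07 from them in culture 3, with 64 of 80 on that side. The 6 not-dim genes of MATa cells lay 0.37 above matched lists in culture 2, with 6 of 6 on that side, and -0.23 from them in culture 1, with 4 of 6. The 26 general stress genes lay 0.14 above matched lists in culture 1 (21 of 26) and -0.14 from them in culture 2 (17 of 26), and the 17 chaperones lay -0.16 from them in culture 2 (12 of 17). The culture 2 shifts of the stress and chaperone lists left the outer range after quantile normalization (-0.06 and -0.09). The stress list also did so after cyclic loess (-0.12) and with dim set below the 50th percentile (-0.11). In these 3 settings the culture 1 shift of the MATa list left it too, at -0.18, -0.17 and -0.20. That shift also left it with log2(signal + 16) (-0.16) and the mean over a gene's probe sets (-0.20). Without letter-coded probe sets such as that of MFA1 it was -0.08. Leaving out a culture took further calls away: the stress list lay 0.03 above matched lists in culture 1 without culture 2 and -0.01 from them in culture 2 without culture 1, the chaperones -0.12 without culture 3 and -0.10 when taken as a list mean, and the MATa list -0.14 in culture 1 without culture 2. The ribosomal protein shifts and that of the MATa list in culture 2 stayed in the outer range with a culture left out. The ribosomal protein shift in culture 3 was then -0.08 without culture 1 and -0.02 without culture 2, and the shifts in culture 2 came down to 0.07 without culture 3 for ribosomal proteins and 0.17 without culture 1 for the MATa list.

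Deviations of a gene from its mean over the 3 cultures are given in log2 with arrays at a common median. The stress gene HSP30, a plasma membrane heat shock protein, deviated by 0.84 in culture 1. HSP12 deviated by 0.37 in culture 1 and -0.32 in culture 2, and the glutamate decarboxylase GAD1 by -0.75 in culture 2. SPI1, the most variable stress gene as deposited, went the other way, by -0.15 in culture 1 and 0.06 in culture 2. Of the chaperones, SSA1 deviated by -0.30 and the heat shock factor gene HSF1 by -0.55 in culture 2, against 0.28 for HSP10. These deviations are not matched on signal. Outside both lists, TDH3 (0.53 in culture 1, -0.35 in culture 2) and CCW12 (0.47, -0.36) deviated at least as far as HSP12, and RPS21A (0.28, -0.09) less. MFA1 carried the widest deviations of its list, -1.10 in culture 1 and 0.77 in culture 2, beside 0.39 for the protease BAR1, 0.29 for the agglutinin subunit AGA2 and 0.10 for STE2 in culture 2. HSP30, GAD1, BAR1 and AGA2, and among metabolic and metal-related genes IZH2, CCC2, SIT1, CAR2, CAR1, PDC5, RIP1, COX7 and TIR4, were picked after their values were seen.

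Metabolic and metal-related lists departed in single cultures. Zinc genes lay -0.19 from matched lists in culture 1, with 9 of 13 on that side, IZH4 deviating by -0.69, IZH2 by -0.49 and ZPS1 by -0.22, while ZRT1 deviated by 0.27. Iron genes lay 0.19 above matched lists in culture 3 (11 of 14), with the siderophore transporters ARN1 and SIT1 at 0.43 and 0.33, the copper pump CCC2 at 0.40 and FET3 at 0.32. Nitrogen genes lay -0.17 from matched lists in culture 2 (13 of 19), with the arginine catabolic genes CAR2 and CAR1 at -0.94 and -0.56 and GAP1 at -0.50. There MEP2 deviated by -0.07, and GDH2, the most variable of the list as deposited, by 0.16. Fermentation genes lay 0.21 above matched lists in culture 3 (6 of 6, PDC5 at 0.38, ADH1 at 0.21), and respiratory chain genes -0.10 from them (13 of 19, COX7 and RIP1 at -0.21). Hypoxic genes lay 0.22 above matched lists in culture 1 (6 of 9), with TIR4 at 0.76, TIR3 at 0.63 while PAU23, listed under its synonym DAN2, deviated by 1.13 in culture 1, 0.69 in culture 3 and -1.82 in culture 2. Without TIR, DAN and PAU members the other 11 measured hypoxic genes, 8 of them dim, lay -0.08 from matched lists in culture 1, short of the outer range. Each of these shifts left the outer range without 1 or other of the remaining cultures, the zinc list at -0.06 without culture 2 and -0.10 without culture 3, the nitrogen list at -0.09 without culture 1, the fermentation list at 0.16 without culture 1 and 0.13 without culture 2, the respiratory chain at -0.08 without culture 1, the iron list at 0.11 without culture 2 and the hypoxic list at 0.04 without culture 3. Taken as a list mean, the respiratory chain lay -0.05 from matched lists and left the outer range. So did the hypoxic list at 0.13 with dim set below a mean signal of 12 and the fermentation list at 0.17 with log2(signal + 16).

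These 13 pairs of a list and a culture had medians in the outer 0.5% at either end of 10000 random lists of the same size and matched signal. For lists of independently varying genes about 0.93 of the 93 pairs tested would lie there. Members of a list can vary together, and the 3 deviations of a gene balance each other. The 93 pairs are thus not separate, and 0.93 is no expected number for these lists. The percentiles describe these arrays and are no test of a difference between cultures, for which there is no error within a culture. With culture 1, 2 or 3 left out, 8, 6 and 8 of 62 pairs lay in that outer range, of which 5, 3 and 6 were among the 13. With 2 cultures the deviations of a list mirror each other, so these pairs are not separate. Of the 31 tested lists the other 21 stayed out of the outer range in every culture in the main setting. Glycolysis, the tricarboxylic acid cycle, storage carbohydrate and ribosome biogenesis were among them. Some other settings brought in pairs outside the 13. With list means 15 pairs lay in the outer range, 11 of them among the 13, and after quantile normalization 11, of which 10 were. A further 6 lists had too few not-dim members.

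**Figure D3:**
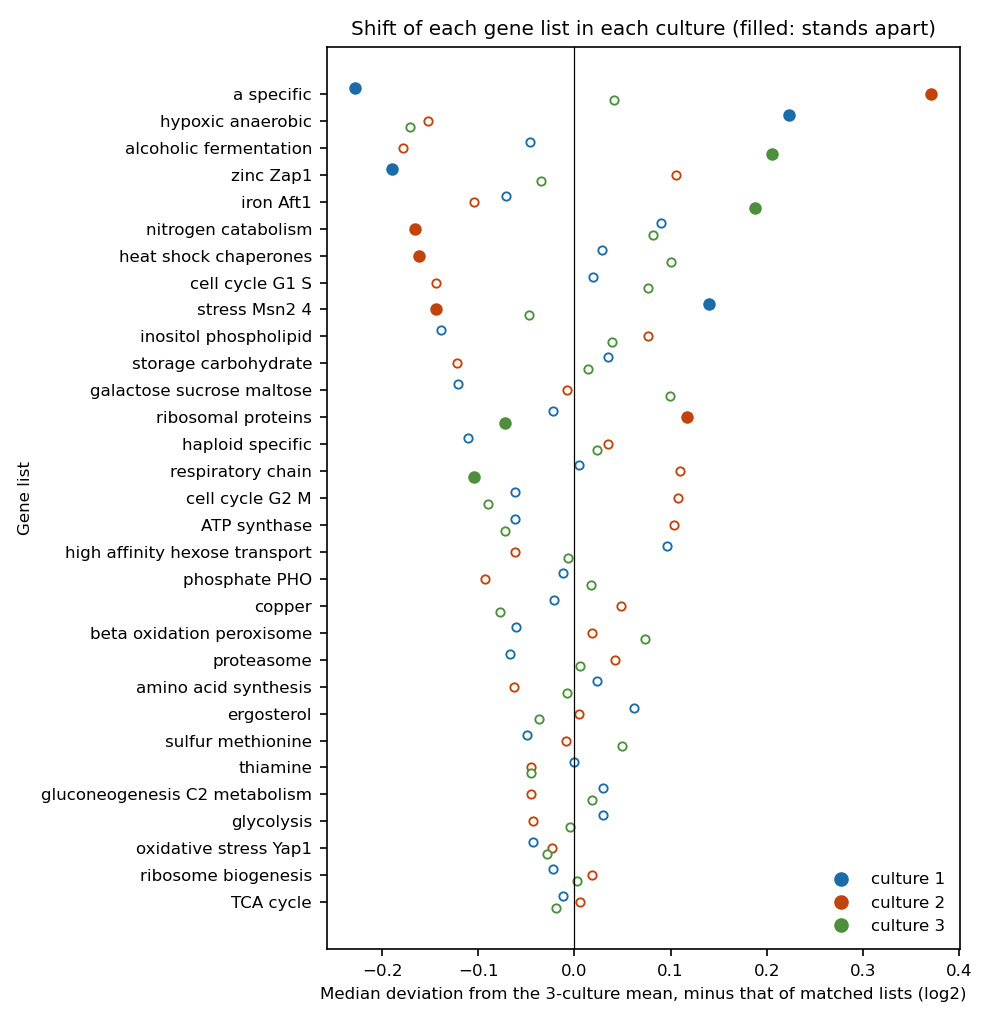
Shift of each of the 31 tested gene lists in cultures 1, 2 and 3, as the median deviation of its not-dim members from their 3-culture mean minus that of matched random lists (log2 axis), with filled points for the 13 pairs in the outer range. The MATa list reaches 0.37 in culture 2 and -0.23 in culture 1, and the hypoxic list 0.22 in culture 1.

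In variability over the 3 cultures, zinc genes, ribosomal protein genes and MATa genes had a larger median SD of deposited log2 signal than matched lists, 0.76, 0.56 and 0.84 against 0.64, 0.49 and 0.60. General stress genes had a smaller one, 0.47 against 0.59. Percentiles among random lists were 99.28, 100, 99.95 and 0.06, in the order zinc, ribosomal protein, MATa and stress. On this scale the SD is made mostly of the array-wide shift. At a common median the stress genes were instead among the more variable lists, with 0.26 against 0.17, as were MATa genes with 0.39 against 0.18. Proteasome genes were less variable, with 0.12 against 0.17. The other 2 lists were then called neither: zinc genes had 0.22 against 0.18 (percentile 87.48). Ribosomal protein genes lay on the other side, with 0.16 against 0.19 (percentile 2.99). The MATa list alone was more variable in 14 of 15 alternative settings, the exception being the one without culture 2. These settings do not include plain-named probe sets only, which would leave out the letter-coded probe set of MFA1.

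Control probe sets gave the state of RNA and labelling on each array. The ratio of the 3' to the 5' actin probe set was 1.43, 1.27 and 1.23 in cultures 1, 2 and 3, and that of SPT15 was 1.94, 1.65 and 1.59. The middle SPT15 probe set read 214, 795 and 403, above the 3' set at 133, 328 and 204. Signal therefore did not fall steadily from 3' to 5', and the SPT15 ratio is no plain measure of RNA state. No ratio is given for SRB4, whose 5' probe set lay under the limit for nonspecific signal on every array. The median of the 9 bacterial hybridization control probe sets was 81.2, 131 and 101. Their log2 ratio of culture 2 over culture 1 lay between 0.06 and 0.69, so that 90.7% of the not-dim yeast genes had a larger ratio than the highest of these controls. The 4 mouse control probe sets stayed at or under 3.00, 1.93 and 2.76.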

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

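No paired analysis was possible because there is 1 group. Scaling to the hybridization controls, the use of plain-named probe sets alone and a floor at the highest sense-strand control were chosen after seeing the data, and the other alternatives were planned. The median SD of log2 signal went from 0.63 as deposited to 0.180 at a common median, 0.177 after quantile normalization, 0.177 after cyclic loess and 0.339 when scaled to the hybridization controls, and to 0.307 without culture 1, with values of 0.307 to 0.857 over the settings that leave out a culture. The count of genes over 2-fold went from 2989 to 138, 139, 133 and 441 in the same order, and lay between 125 and 2873 with a culture left out. These alternatives remove the array-wide shift by construction, in part for the controls, and leaving out culture 1 removes the array with the lowest signals. The number of lists with most members dim went from 5 to 2 with the limit at the 10th percentile, 11 at the 50th and 2 at a mean signal of 12, which follows from the limit itself. Pairs of a list and a culture in the outer range numbered 6 to 8 with a culture left out, when fewer pairs were tested. None of the 13 pairs reversed. Both ribosomal protein pairs and the MATa list in culture 2 stayed in all 15 alternatives, though at -0.02 instead of -0.07 (ribosomal proteins, culture 3), 0.07 instead of 0.12 (ribosomal proteins, culture 2) and 0.17 instead of 0.37 (MATa) at the smallest with a culture left out, the MATa list in culture 1 stayed in 8 of 15, and the other pairs stayed in 11 to 14. Lists more variable than matched lists numbered 1 to 3 with a culture left out. Less variable lists numbered 0 after cyclic loess, 2 with dim below the 50th percentile, 2 with log2(signal + 16) and 3 with any of the cultures left out, and the cause was not tested. The highest 3' to 5' ratio of actin lay between 1.27 and 1.43 with a culture left out. Signal over background limits the dim genes: sense-strand bacterial controls reached 23.2, 26.3 and 24.2 in cultures 1, 2 and 3, so that signals of that size or less can be nonspecific.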

Other observations

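All tests in this part, and the genes named, were chosen after the results were seen. With arrays at a common median, 66 genes lay over 1 (log2) above or below both other cultures, and 44 of these were low in culture 2. These counts hold relative to the array-wide shift: as deposited 3 of the 44 (MEF1, GTT2 and PAU23) lay that far below both others and 16 were lowest in culture 1, and 12 of the 44 did so when scaled to the hybridization controls. Besides MEF1 (9.18-fold under the nearer of the other cultures), PAU23 (5.71-fold) and GTT2, for which no fold is given because its 16.6 in culture 2 can be nonspecific, they included the mitochondrial iron-sulphur protein gene ISA1 (3.76-fold), the cytochrome c oxidase subunit gene COX12 (3.26-fold), the osmosensing response regulator gene SSK1 (3.33-fold), the transcription factor subunit gene SSL1 (3.36-fold), and genes of amino acid metabolism, CYS3 (2.65-fold), CAR2 (2.44-fold), THR1 (2.24-fold) and ILV6 (2.17-fold). No gene was that far above both others in culture 2 at a common median, against 104 as deposited and 4 when scaled to the hybridization controls. At a common median only TPM1 stood apart in culture 3, 3.98-fold low, while 8 genes were that high in culture 3 as deposited and 10 when scaled to the hybridization controls.

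In culture 1, 16 genes stood over 1 (log2) higher than in both other cultures at a common median, of which 11 were highest in culture 1 as deposited, none by over 1, and 3 passed 1 when scaled to the hybridization controls. Among them were 7 seripauperin genes, members of a large subtelomeric family known from anaerobic growth, of which PAU13 lay 3.30-fold, PAU15 2.68-fold and PAU10 2.60-fold above the nearer culture. With them stood TIR4 (2.07-fold), HSP30 (2.16-fold), the peroxiredoxin gene TSA2 (2.19-fold), the aquaporin gene AQY1 (2.32-fold) and the spore wall gene SPS100 (2.08-fold). All 10 not-dim PAU genes were higher in culture 1 than in both other cultures at a common median, by a median deviation of 0.83, and after quantile normalization and cyclic loess, as were 9 of 10 when scaled to the hybridization controls (median 0.50) and 6 of 10 as deposited (median 0.17). As deposited, TIR4 read 139, 138 and 116 and PAU7 169, 162 and 137 in cultures 1, 2 and 3, while PAU13 read 254, 171 and 132, and HSP30 with 627, 670 and 407 and SPS100 with 310, 345 and 214 were highest in culture 2. The 5 genes low in culture 1 were MFA1 (2.69-fold), SUF23, YNCP0023W, the zinc-linked IZH4 (2.02-fold) and YLL054C, which no longer stood apart with signals floored at the sense-strand controls. As deposited 816 genes lay that low in culture 1, and 77 when scaled to the hybridization controls.

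For the array-wide difference between cultures 1 and 2, a factor common to every probe set, such as scanner gain, is argued against as the whole cause, because the median yeast log2 ratio of 1.21 lies above all 9 hybridization controls, the highest at 0.69. More labelled yeast target on the array of culture 2 remains a hypothesis. That 90.7% of yeast genes exceeded that control is the same comparison and no separate evidence for it. The 3' probe set of the bacterial Dap control read 50.6, 106 and 49.1 in cultures 1, 2 and 3. It was the only Dap set above the limit for nonspecific signal on all arrays. Whether yeast target alone differed, or an unequal amount of the control mixture with or without a scanner factor, stays open, and no biological explanation was tested, as the design gives none.

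For the 44 probe sets low in culture 2, a signal-dependent difference between arrays is argued against, since 43 of 44 stayed over 1 below both other cultures after cyclic loess, and so is noise of weak probe sets, since their median signal lay at percentile 57.5 of not-dim genes (bootstrap 95% interval 44.3 to 72.9). The low probe sets lay close together: 8 of them (MEF1, GTT2, PAU23, ISA1, SSL1, SSK1, COX12 and TPO1), with 7 of the 8 largest drops, fell within a run of 150 probe set numbers, against a mean of 4.33 in the densest run of random sets, and 3 pairs had neighbouring numbers (PAU23 and COX12, SSL1 and SSK1, TPO1 and ISA1) against 0.29. As many as 8 were reached in 17 of 10000 random sets. Loss of that stretch of chromosome XII is argued against, since the other 64 not-dim genes in the run had a median deviation of -0.014 in culture 2 (bootstrap 95% interval -0.061 to 0.050). A flaw in a part of the array cannot be told apart from gene position, since numbers lie within 2 of each other for 77.2% of neighbouring genes and the array layout was not used here, and no biological explanation was tested.

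The 16 probe sets high in culture 1 were weighed last. Cross-hybridization within the seripauperin family may multiply 1 signal over its members and cannot be told apart for the PAU genes, since 0 of the 7 have a probe set named without a family code. By their names 8 of the 16 lie outside the PAU, TIR and DAN genes, so it could not account for the whole group. That follows from the names and is no separate test. Lower oxygen supply in culture 1 is neither borne out nor excluded, because the other 11 measured hypoxic genes, 8 of them dim, lay at percentile 17.0 of matched lists in that culture. The labels give dissolved oxygen above 80% of air saturation for each culture, which speaks against a shortage, and values per culture were not analysed here.

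The hypothesis of an extra or missing chromosome in a culture was tested on 3923 genes with a negative result, the largest absolute median deviation of the 16 chromosomes being 0.085 (log2, chromosome X, culture 1).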
